A study of Mus musculus with 6 samples.

How the data were processed

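Messenger RNA was sequenced from 6 libraries of mouse cells labelled ADSCs, 3 carrying a scrambled hairpin and 3 carrying a hairpin against Ifit1. Per the labels' protocols, RNA was taken up in Trizol, mRNA was captured on beads and fragmented by heat, and cDNA was end-repaired, A-tailed and ligated to adapters. Per the labels, the libraries fall into 3 batches, and each batch holds 1 scrambled and 1 knockdown library. The labels do not say whether the libraries came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

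The authors deposited 1 table with 19877 genes and 1 value in FPKM (fragments per kilobase of gene and M fragments) per gene and library, beside a description and pathway annotation of each gene. The submitters' processing notes name the builds GRCm38, mm10 and GRCm39 without saying which step used which. The aligner, the counting tool, its strand setting and the versions are not given in the sources used here. No filter or scaling between libraries beyond the FPKM is recorded.

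The depth was read from the values. Within a library, a gene's FPKM is a whole multiple of the value of 1 fragment, and whole numbers explained the values above 0 of 19877 of the 19877 genes within 0.002 of a whole number. A gene above 0 in only 1 library always fits, and 1 above 0 in 2 or 3 libraries nearly always, so the share is no check for such genes. The smallest whole numbers that fitted were taken, so fragments of low genes are understated where their counts share a factor. The fragments recovered this way summed to 40.6, 37.1 and 37.7 M in scrambled libraries 1, 2 and 3 and to 36.5, 32.2 and 40.2 M in knockdown libraries 1, 2 and 3. The median tested gene had between 1307 and 1723 fragments in a library, and counting error was a part of the spread between libraries. These sums cover the listed genes, and reads outside them were not used here. No 2 libraries agreed within sampling noise, since the chi-square per gene between libraries of a group ran from 3.16 to 12.5, where 1 is the value of sampling noise alone.

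Genes with an FPKM of at least 1 in at least 3 of the 6 libraries, whatever their group, were tested (10311 genes). The FPKM values were changed to log2(FPKM + 0.5). A fold change on this scale understates the change of low genes. Knockdown and scrambled libraries were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated variance with a trend on the mean level, two-sided test), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05 on the adjusted p. A second count asked in addition for a log2 fold change of at least 1 in size. The FPKM are not counts, so no count model gave the main result. An error after a log2 fold change is its standard error, and an error after an FPKM is the SD over 3 libraries.

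Before the data were examined, 29 gene lists and the main tests and alternatives were fixed. The lists cover interferon-stimulated genes, antigen presentation by MHC class I, cytokines and chemokines, cytosolic ribosomal proteins, translation factors, the integrated stress response, ribosome biogenesis, myogenic, cardiac and smooth muscle genes, mesenchymal stromal markers, adipocyte and osteogenic or chondrogenic differentiation, extracellular matrix, TGF-beta responsive genes, angiogenic and paracrine factors, cell cycle, p53 targets and senescence, hypoxia and glycolysis, nuclear and mitochondrial genes of oxidative phosphorylation, folding in the endoplasmic reticulum, immediate early genes, histones, and markers of macrophages, lymphocytes and mast cells, endothelium, epithelium and mesothelium, and Schwann or neural cells. Ifit1 itself was kept out of the interferon list. Lists with at least 3 tested genes (25 lists) were tested with camera in limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the 25 lists. Members were counted by their adjusted p over all tested genes and, separately, adjusted over the list alone. Genes of the mitochondrial genome stand in the table without their usual prefix, and the 13 members were matched through their Entrez numbers, all 13 on the mitochondrial chromosome.

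The genes named were set by rule. They are Ifit1 and its family, the 10 largest rises and the 10 largest falls among genes past the threshold, and up to 4 tested members of smallest p from each list. For the rises and falls, the groups had to be separated, the mean FPKM of the higher group had to be at least 1, and unnamed predicted genes and pseudogenes were left out. Some genes that met these rules are withheld and are not named. Gene positions, transcript GC content and gene types came from GENCODE M21 on GRCm38, to which 10001 of the 10311 tested genes matched by symbol (97.0%). Gene lengths were those implied by the value of 1 fragment.

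Because the labels say that libraries of 1 number share a batch, the number pairs the libraries. A fit with batch as a block was planned as the alternative. The deviations of same-numbered libraries from their group means correlated at 0.09, 0.01 and 0.19 across genes for batches 1, 2 and 3, and those of other pairs at −0.17 to 0.11.

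Alternatives set before the data were seen were pseudocounts of 0.1 and 1, no filter, a mean FPKM of at least 5, rescaling to TPM (each library divided by its sum of FPKM), median centring, quantile normalization, the block, leaving out each library, limma without the trend and limma with weights per library. After the data were seen, 2 alternatives were added, limma-voom on the recovered fragments and removal of each library's trend with mean level, gene length and GC content (natural splines). Alternatives meant for a table of counts were not run, since the table holds FPKM.

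The procedure was tested on simulated data. Counts were drawn for the 10311 genes from the means and depths of the real libraries for the comparison of knockdown with scrambled, with 50 genes changed at each of 4 fold sizes. It recovered 16.0% of the genes changed 1.2-fold, 92.0% of those changed 1.5-fold, 98.0% at 2-fold and 100% at 4-fold, with 12 false calls among 10081 unchanged genes. A list of genes raised 1.2-fold was recovered at an adjusted p of 4.04e-15, and 0 of 20 lists of unchanged genes were called. In the simulation genes vary independently of one another, which real genes do not. Its spread was estimated from fragments not scaled for depth, so depth differences counted as spread between libraries of a group. Far fewer genes were changed than passed in the real comparison. The recovered shares therefore need not hold for the real libraries.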

Results

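Gene expression was compared between mouse ADSCs carrying a scrambled hairpin and ADSCs carrying a hairpin against Ifit1 (3 libraries each). ADSC is a common abbreviation for adipose-derived stem cells, the multipotent stromal cells of fat tissue, and the labels give only the abbreviation. The series' title places the cells in mesenchymal stem cell therapy of myocardial infarction and names translational suppression and myogenic differentiation as the processes of interest. IFIT1 is an interferon-induced protein that binds the ends of foreign RNAs and limits their translation. The question asked of these data was which transcripts differ when Ifit1 is knocked down. Between 32.2 and 40.6 M fragments were recovered per library.

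Knockdown libraries held fewer transcripts of low abundance than scrambled libraries. Between 3476 and 3868 genes were listed at 0 in a knockdown library and between 3013 and 3188 in a scrambled library, and the knockdown library with 40.2 M fragments still listed more genes at 0 than the scrambled library with 37.1 M. Genes with a mean FPKM under 0.02 (4830 genes) took 96.6 ± 2.72 of each 1 M fragments in knockdown and 131 ± 4.45 in scrambled libraries (SD, n = 3 each), a ratio of 0.735. The ratio was 0.802 for genes of FPKM 0.5 to 1, 0.858 for 1 to 3, 0.930 for 3 to 10, 0.997 for 10 to 100 and 1.04 for 100 and over. The 3 knockdown libraries lay below the 3 scrambled ones in each class under FPKM 10. With 3 libraries against 3 an exact permutation test cannot go below p = 0.1.

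**Figure D1:**
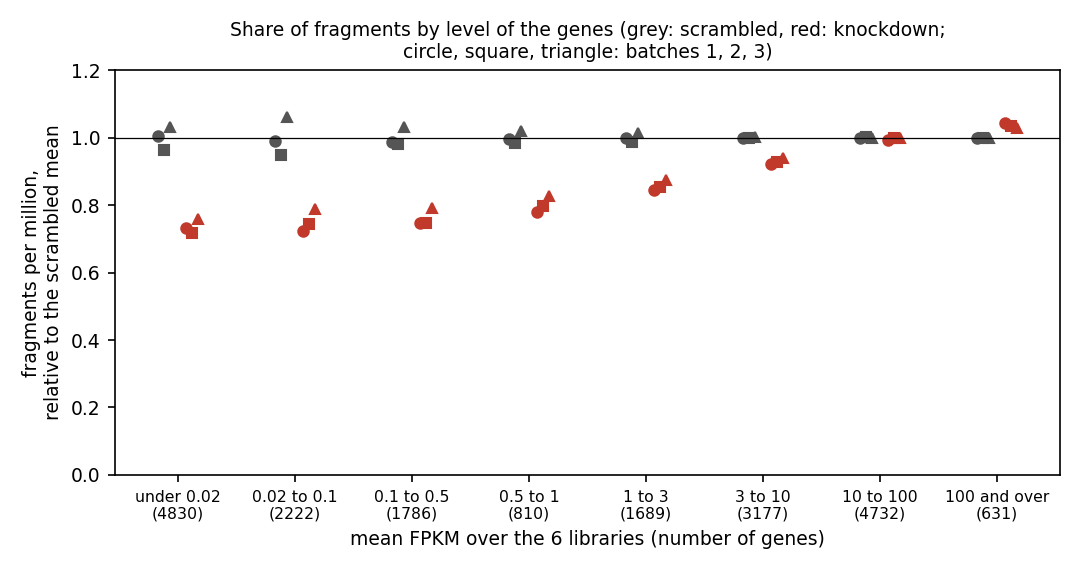
Fragments, per 1 M of a library, taken by genes of each level class (mean FPKM over the 6 libraries, number of genes in brackets), relative to the mean of the scrambled libraries. Each point is 1 library, grey for scrambled and red for knockdown, and the knockdown ratio runs from 0.735 in the lowest class to 1.04 in the highest.

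Ifit1 RNA was lower in all 3 knockdown libraries. Ifit1 (Entrez 15957) lies on chromosome 19, positions 34640871 to 34650009 of GRCm38, plus strand, with 2 exons, in a cluster with its family members, and the position targeted by the hairpin is not given in the sources used here. Its level was 4.90, 3.75 and 4.97 FPKM in scrambled libraries 1, 2 and 3 and 1.76, 1.48 and 1.51 FPKM in knockdown libraries 1, 2 and 3. The scrambled mean of 4.54 ± 0.685 FPKM was 2.87 times the knockdown mean of 1.58 ± 0.151 FPKM (SD, n = 3 each). The log2 fold change was −1.27 ± 0.11 (limma adjusted p = 5.71e-05). Within batches 1, 2 and 3 the log2 difference was −1.26, −1.10 and −1.44.

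Ifit2 was also lower, and Ifit3 and Ifit3b were too low for the main test. Ifit2 went from 6.07 ± 0.634 to 4.93 ± 0.364 FPKM (log2 fold change −0.27 ± 0.08, limma adjusted p = 0.0193), a call that was lost without the filter, under median centring, under quantile normalization, with the level, length and GC trend removed and without scrambled library 3 or knockdown library 1. Ifit3 averaged 1.17 ± 0.393 FPKM in scrambled and 0.452 ± 0.267 in knockdown libraries, and Ifit3b 0.370 ± 0.0590 and 0.108 ± 0.0868. Both were below the filter. Without the filter Ifit3 did not pass (log2 fold change −0.82, limma adjusted p = 0.0586) and Ifit3b passed (−0.52, adjusted p = 0.0187). They are near-identical copies between which reads may be split uncertainly. Ifit1bl1 and Ifit1bl2 were near 0 in both groups, with means of at most 0.0131 FPKM.

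**Figure D2:**
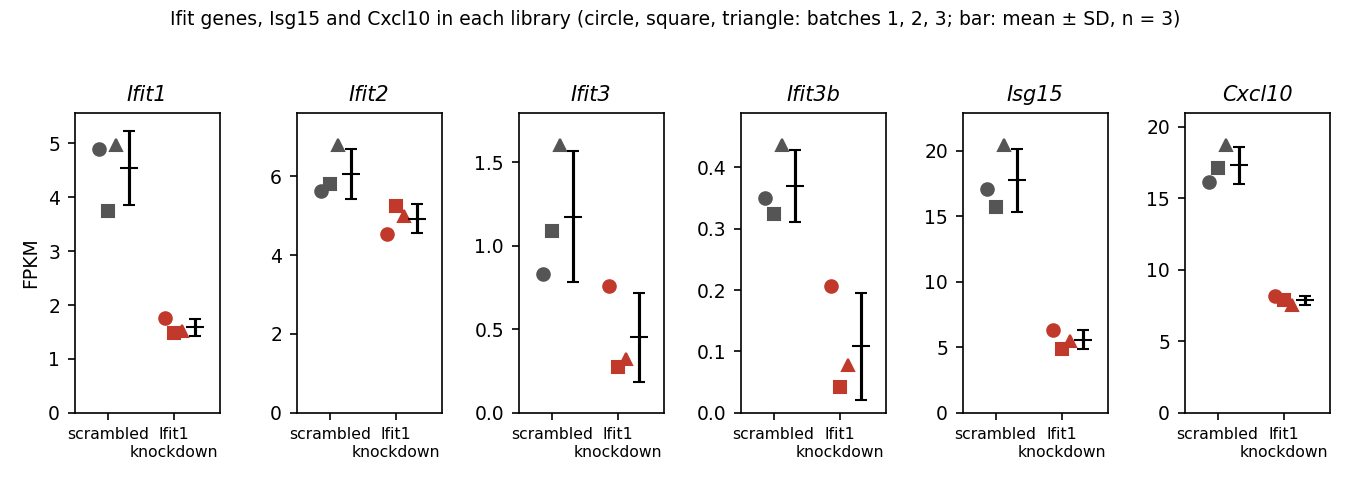
FPKM of Ifit1, Ifit2, Ifit3, Ifit3b, Isg15 and Cxcl10 in each library, with the mean and SD of the 3 libraries of a group beside the points. Ifit1 lies between 3.75 and 4.97 FPKM in scrambled and between 1.48 and 1.76 FPKM in knockdown libraries.

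About as many tested genes passed the threshold as did not, and those that did not are not shown to be unchanged. Of 10311 tested genes, 5255 (51.0%) passed the threshold, 2046 higher and 3209 lower in knockdown, and 5944 had an unadjusted p under 0.05 (limma). Most of these changes were small, with a median size of 0.26 on the log2 scale among called genes, and 128 genes changed at least 2-fold, 16 up and 112 down. The groups were separated for 6302 genes (61.1%), where chance gives 10%. Of the 5255 called genes, 5235 (99.6%) had the pooled direction in all 3 batches, which largely follows from their being called in these same libraries. The first principal component held 80.5% of the variance and parted the groups. The share of called genes that were higher was 38.9% and depended on the scaling: it was 27.6% after rescaling to TPM (1540 higher, 4035 lower), 56.7% after median centring (3001 and 2293), 52.4% after quantile normalization (2486 and 2256) and 52.0% with the trend in level, length and GC content removed (2469 and 2278). Of the 5255 calls, 4 were called in the opposite direction under quantile normalization and 4 with that trend removed. The count of genes changed at least 2-fold moved to 214 with a pseudocount of 0.1, 199 after rescaling to TPM, 249 with limma-voom and 47 with a mean FPKM of at least 5.

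On the log2(FPKM + 0.5) scale Serpinb2 and Smoc2 had the largest rises. Serpinb2, an inhibitor of plasminogen activators, rose from 1.48 ± 0.528 to 10.1 ± 4.26 FPKM (log2 fold change 2.38 ± 0.29, limma adjusted p = 0.000283). Smoc2, a matricellular calcium-binding protein, rose from 1.64 ± 0.366 to 9.66 ± 1.27 FPKM (2.26 ± 0.13, adjusted p = 1.89e-05). Id1, an inhibitor of basic helix-loop-helix transcription factors and a target of BMP signalling, rose from 15.9 to 41.6 FPKM (1.35 ± 0.07, adjusted p = 1.49e-05). Ccn2, a matricellular protein formerly called CTGF, rose from 145 ± 6.38 to 324 ± 76.2 FPKM (1.13 ± 0.14, adjusted p = 0.000315). U90926 rose from 0.214 ± 0.225 to 2.49 ± 0.846 FPKM, and its log2 fold change of 2.06 ran from 1.51 to 3.75 over the alternatives. Its ratio of means was above that of Serpinb2 but rests on scrambled values of 0.472, 0.0574 and 0.113 FPKM. The log2 fold change was 1.33 for Snhg9, 1.30 for Pcolce2, an enhancer of procollagen processing, 1.22 for Ccbe1 and 1.16 for the homeobox gene Dlx2. Snhg9 lost its call without the filter (adjusted p = 0.0652) and is annotated as antisense, so its reads cannot be told from those of an overlapping gene without strand.

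The largest falls included 4 members of the integrated stress response list. Trib3, a pseudokinase, fell from 27.6 ± 3.12 to 5.64 ± 0.569 FPKM (log2 fold change −2.19 ± 0.09, limma adjusted p = 7.51e-06). Cth, which makes cysteine from cystathionine, fell from 21.8 ± 3.21 to 5.03 ± 0.815 FPKM (−2.01 ± 0.12, adjusted p = 1.89e-05). Fgf21, a stress-induced hormone, fell from 1.93 ± 0.592 to 0.0798 ± 0.0435 FPKM (−2.04 ± 0.16, adjusted p = 4.86e-05). Its mean was 24.2 times higher in scrambled libraries, and the log2 value of so low a gene depended on the pseudocount, running from −4.42 to −1.42 over the alternatives. Ddit4, an inhibitor of mTORC1, fell from 87.4 ± 4.80 to 23.9 ± 4.42 FPKM (−1.87 ± 0.12, adjusted p = 2.1e-05). H19, an imprinted non-coding RNA, fell from 4.47 ± 0.452 to 0.702 ± 0.206 FPKM (−2.06 ± 0.13, adjusted p = 2.1e-05). The log2 fold change was −1.90 for Cdsn, −1.88 for Mgarp, −1.78 for the acyl-CoA thioesterase Acot2, −1.77 for the peptide hormone gene Adm2 and −1.77 for Lrrc17.

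Nearly all tested ribosome biogenesis genes rose, and most translation factors and ribosomal protein genes that passed the threshold were higher. Of 35 tested ribosome biogenesis genes, 34 rose and 0 fell (median log2 fold change 0.37), among them Ncl (nucleolin, 0.36), Npm1 (nucleophosmin, 0.33), Nop56 (0.41) and Rrp12 (0.72). Of 47 translation initiation and elongation factors, 33 rose and 3 fell (median 0.17). Eif5 (0.29), Eif4a1 (0.26) and Eef1d (0.35) rose and Eif3c fell by 0.32. Of 78 cytosolic ribosomal protein genes, 58 rose and 0 fell, by a small amount (median 0.12), among them Rps2 (2457 to 2820 FPKM, 0.20, not past the threshold under quantile normalization), Rpl6 (0.21), Rps12 (0.23) and Rpl8 (0.22). Adjusted over the list alone, 34, 33 and 59 genes of the 3 lists rose. Camera adjusted p was 5.22e-19 for ribosome biogenesis, 3.81e-09 for the translation factors and 6.42e-15 for the ribosomal proteins, and adjusted p = 0.284 for each of the 3 with an estimated correlation. The ribosomal protein call was lost under quantile normalization (median 0.02, adjusted p = 0.411) and with the level, length and GC trend removed (median −0.00, adjusted p = 0.989), where its sign also turned. In place of 58 and 0, 18 ribosomal protein genes rose and 7 fell under quantile normalization, and 14 rose and 15 fell with the trend removed. Ribosomal protein genes have many processed pseudogenes, to which reads may have been assigned.

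Interferon-stimulated genes that passed the threshold all fell. Of 44 listed genes, 28 were abundant enough to test, and all 28 fell, 10 of them at least 2-fold (median −0.87, camera adjusted p = 5.84e-10, and adjusted p = 0.284 with an estimated correlation), and all 28 passed adjusted over the list alone. The count was 26 of 28 under median centring and under quantile normalization, 25 of 27 with the level, length and GC trend removed and 34 of 44 without the filter, with 0 genes higher in each. Isg15, a ubiquitin-like modifier, fell from 17.7 ± 2.42 to 5.57 ± 0.737 FPKM (−1.59 ± 0.11, limma adjusted p = 2.59e-05). The transcription factor Stat2 (−0.86), the RNA sensor Rigi (−0.97) and Parp9 (−0.96) also fell. The median of the list within batches 1, 2 and 3 was −0.63, −0.85 and −1.04. Of 16 genes of antigen presentation by MHC class I, 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of −0.53 (camera adjusted p = 9.38e-05, and adjusted p = 0.284 with an estimated correlation). The peptide transporter Tap2 fell by 1.54 and the class I heavy chain H2-K1 by 1.29 on the log2 scale, from 41.8 ± 3.37 to 16.8 ± 1.18 FPKM. Psme2, a proteasome activator subunit, fell by 0.63, and H2-Q4 by 1.62, though reads of the H2-Q genes may be shared between copies. Of 12 cytokine and chemokine genes, 2 rose, 5 fell and 5 did not pass, and the list as a whole did not pass (median −0.28, camera adjusted p = 0.591). The counts were the same adjusted over the list alone. With batch as a block 4 rose and 7 fell, without knockdown library 3 the counts were 2 and 8, and under quantile normalization 2 and 3. The interferon-inducible chemokines Cxcl10 (−1.09) and Ccl5 (−1.43) fell, while Csf1 (0.49) and Ptgs2, the prostaglandin synthase COX-2 (0.64), rose.

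Stress-response and hypoxia genes were lower in knockdown. Of 29 integrated stress response genes, 28 fell and 0 rose (28 adjusted over the list alone), with a median of −0.52 (camera adjusted p = 9.05e-13, and adjusted p = 0.284 with an estimated correlation). The list holds targets of ATF4, and besides Trib3, Cth, Fgf21 and Ddit4 it includes the asparagine synthetase Asns (−0.63) and the mitochondrial folate enzyme Aldh1l2 (−1.54). The median was −0.52, −0.46 and −0.55 within batches 1, 2 and 3. Of 26 hypoxia and glycolysis genes, 23 fell and 0 rose (24 and 0 adjusted over the list alone), with a median of −0.38 (camera adjusted p = 7.41e-09, and adjusted p = 0.284 with an estimated correlation). The pyruvate dehydrogenase kinase Pdk1 (−1.42), Bnip3 (−1.35), Ndrg1 (−1.14) and the phosphofructokinase Pfkl (−0.59) fell. The 23 tested genes of protein folding in the endoplasmic reticulum went both ways, 5 up and 9 down (the same adjusted over the list alone), and the list did not pass (median −0.03, camera adjusted p = 0.693), although it passed under quantile normalization and with the level, length and GC trend removed, with 6 up and 5 down under median centring and 3 up and 12 down in each of those 2 settings. Herpud1 (−0.68), Xbp1 (−0.44) and Edem1 (−0.33) fell and Creld2 rose by 0.22.

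**Figure D3:**
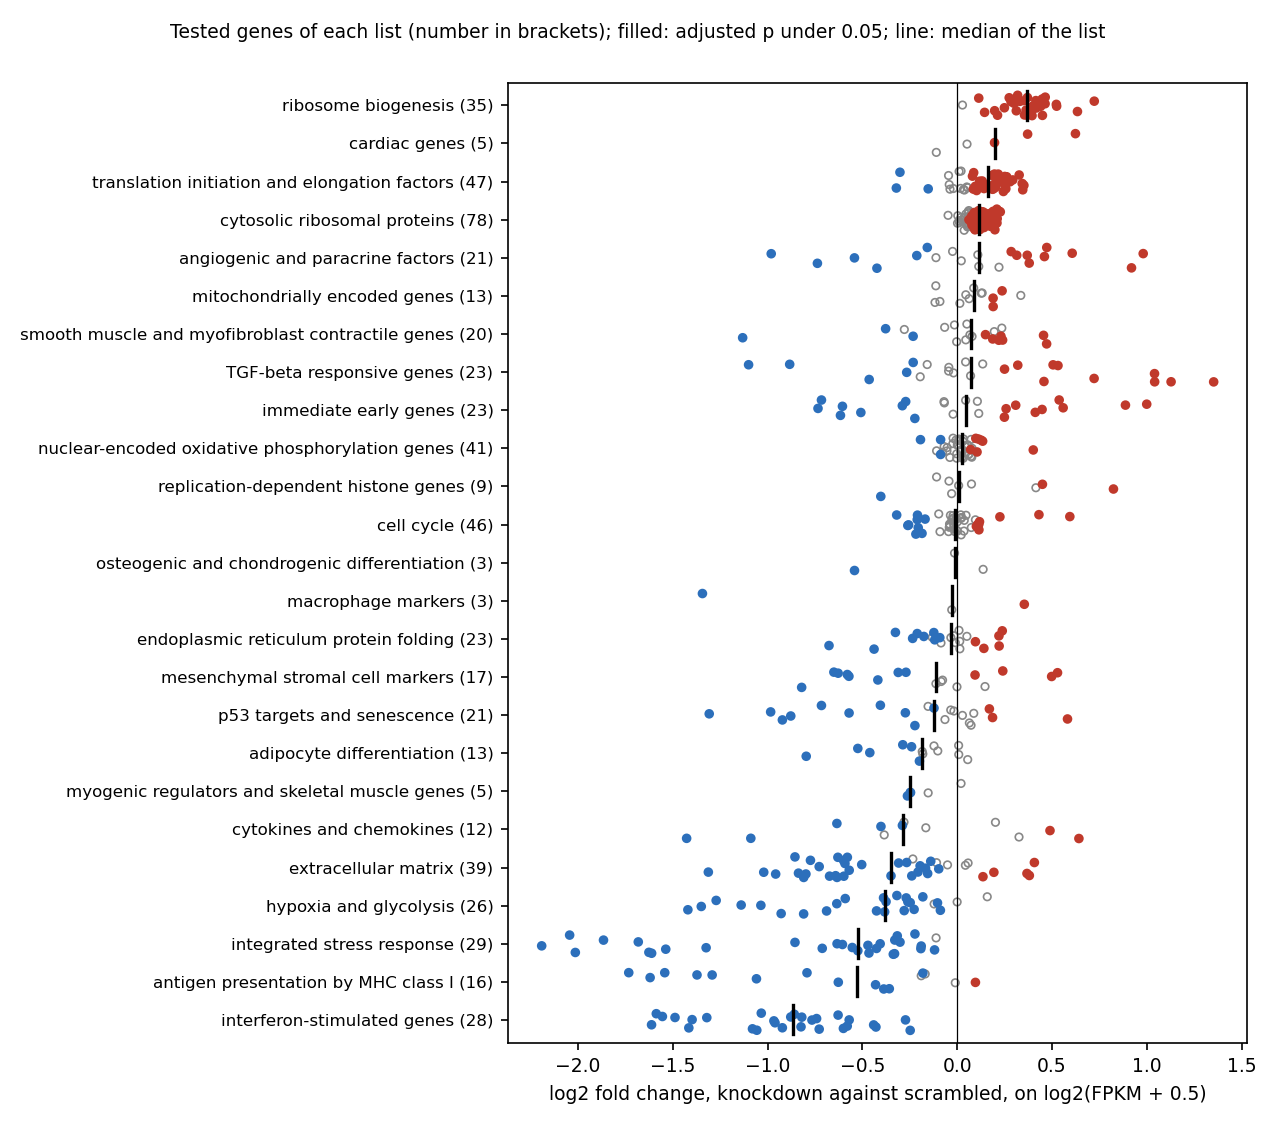
Log2 fold change of each tested gene, by list, on the log2(FPKM + 0.5) scale, with filled points for genes past an adjusted p of 0.05 and a line at the median of the list. The medians run from −0.87 for interferon-stimulated genes to 0.37 for ribosome biogenesis.

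In the main fit 3 of 5 tested skeletal muscle genes fell and 3 of 5 tested cardiac genes rose, and neither list passed. Smooth muscle genes went both ways. Of 25 listed myogenic regulators and skeletal muscle genes, 5 were abundant enough to test, and 3 of them fell (4 adjusted over the list alone). Among them were Six4 (−0.25, limma adjusted p = 0.0190) and Pax3 (−0.25, adjusted p = 0.0361), transcription factors of early muscle precursors. Mef2a stood at −0.15 (adjusted p = 0.0551) and passed after rescaling to TPM (0.0231), without the limma trend (0.0443), with limma-voom (0.0127) and without knockdown library 2 (0.0219). The list did not pass (median −0.25, camera adjusted p = 0.274). The calls of Six4 and Pax3 were lost without the filter, under median centring, under quantile normalization, with the level, length and GC trend removed and without some single libraries. Of the 5 skeletal muscle genes, 0 passed under quantile normalization, and 1 passed, lower, under median centring and with that trend removed. Of 5 tested cardiac genes, 3 rose and 0 fell (the same adjusted over the list alone; median 0.20, camera adjusted p = 0.0671), and the list passed after rescaling to TPM (0.0397) and without knockdown library 3 (0.0352). Without the filter, 4 of 18 cardiac genes rose and 1 fell, and the median was −0.00. The gap junction gene Gja1 (0.37), the calcium pump Atp2a2 (0.20) and the troponin Tnnt2 (0.62, from 1.65 ± 0.237 to 2.83 ± 0.459 FPKM) rose, and Gata6 stood at −0.11 (adjusted p = 0.172), with its sign turned when the level, length and GC trend was removed. Of 20 smooth muscle and myofibroblast genes, 7 rose and 3 fell (the same adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.0389, and adjusted p = 0.492 with an estimated correlation). Srf (0.47), Tpm4 (0.23) and Cnn2 (0.22) rose and the amine oxidase Aoc3 fell by 1.13. That list call was also lost under quantile normalization (adjusted p = 0.423), with the trend removed (adjusted p = 0.345) and without scrambled library 1 (0.0659), scrambled library 2 (0.0818) or knockdown library 1 (0.0740).

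Extracellular matrix genes mostly fell, stromal markers went both ways, and the adipocyte genes that passed in the main fit all fell. Of 39 extracellular matrix genes, 29 fell and 5 rose (the same adjusted over the list alone), with a median of −0.35 (camera adjusted p = 1.02e-05, and adjusted p = 0.284 with an estimated correlation). Col3a1 fell from 204 ± 9.05 to 101 ± 9.41 FPKM (−1.02), and Col5a3 (−1.31), Col5a1 (−0.63) and the fibrillin Fbn1 (−0.60) also fell. Of 17 mesenchymal stromal markers, 4 rose and 8 fell, with Alcam (0.53) and Cd44 (0.50) higher and Ly6a (−0.82) and Thy1 (−0.42) lower (median −0.11, camera adjusted p = 0.321). Of 13 adipocyte genes, 6 fell and 0 rose, among them the desaturase Scd1 (−0.80), Cebpb (−0.52), the lipase Lpl (−0.46) and Dgat1 (−0.24, lost with the level, length and GC trend removed), and the list did not pass (median −0.18, camera adjusted p = 0.0671) except without the filter (adjusted p = 0.0235). Under median centring 6 adipocyte genes fell and 1 rose. Cebpb also belongs to the integrated stress response list. Of 3 tested osteogenic and chondrogenic genes, Spp1 (osteopontin) fell by 0.55, and Sox9 (0.14, adjusted p = 0.0892) and Runx2 (−0.01, adjusted p = 0.815) did not pass (median −0.01, camera adjusted p = 0.954). Sox9 passed under median centring, under quantile normalization, with the level, length and GC trend removed and without scrambled library 2, and the sign of Runx2 turned in the first 3 of these. The counts of these 3 lists were the same adjusted over the list alone.

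Of 23 TGF-beta responsive genes, 10 rose and 5 fell, 4 of the rises at least 2-fold. Besides Id1 and Ccn2, the BMP-responsive Id3 rose by 0.72, while Tgfbi (−1.10) and the receptor Tgfbr2 (−0.88) fell. The list did not pass (median 0.07, camera adjusted p = 0.0671), but it passed after rescaling to TPM (0.0288), without the filter (0.0362), with limma-voom (0.0493) and without scrambled library 3 (0.0403), knockdown library 2 (0.0495) or knockdown library 3 (0.0238). Of 21 angiogenic and paracrine factors, 9 rose and 6 fell, with the follistatin gene Fst (0.98) and Bdnf (0.61) higher and Vegfa lower by 0.98, from 52.2 to 26.2 FPKM. The list did not pass (median 0.11, camera adjusted p = 0.0671) except after rescaling to TPM (0.0288) and without knockdown library 3 (0.0462), and without the filter 7 of 29 rose and 8 fell. Under quantile normalization 12 rose and 3 fell, and with the level, length and GC trend removed 12 rose and 4 fell. The counts of both lists were the same adjusted over the list alone.

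Cell cycle genes moved both ways. Of 46 tested genes, 8 rose and 9 fell (8 and 8 adjusted over the list alone). The balance depended on the scaling, with 3 up and 14 down after rescaling to TPM, 14 and 7 under median centring, 5 and 14 under quantile normalization and 5 and 15 with the level, length and GC trend removed. The ribonucleotide reductase subunit Rrm2 (0.59) and Mybl2 (0.43) rose, and Ccnb2 (−0.32) and Top2a (−0.21) fell. The median of the list was −0.01 and its camera direction was up (adjusted p = 0.571). Of 21 p53 targets and senescence genes, 3 rose and 10 fell (the same adjusted over the list alone), without passing as a list (median −0.12, camera adjusted p = 0.210). The cyclin-dependent kinase inhibitors Cdkn1a (−0.88), Cdkn2b (−0.98) and Cdkn2a (−0.57) and the damage-inducible Gadd45a (−1.31) fell. Of 23 immediate early genes, 9 rose and 8 fell (the same adjusted over the list alone; median 0.04, camera adjusted p = 0.223), with Fosl1 (0.89), Klf2 (1.00) and Myc (0.25) higher and Ier2 lower by 0.51.

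Genes of the respiratory chain changed little. Of 41 nuclear-encoded genes, 7 rose and 3 fell (4 and 1 adjusted over the list alone), with Cycs (0.40), Cyc1 (0.13) and Ndufs7 (0.13) higher and Ndufa2 (−0.19) lower, and the list did not pass (median 0.02, camera adjusted p = 0.0671), although it passed under median centring (0.00263), without the filter (0.0248) and without knockdown library 2 (0.0333). The balance of the nuclear-encoded genes turned with the scaling, with 3 up and 10 down after rescaling to TPM, 18 and 1 under median centring, 4 and 7 under quantile normalization and 3 and 11 with the level, length and GC trend removed. Of 13 genes of the mitochondrial genome, ND1 (0.19), ND2 (0.24) and ND4 (0.19) rose and 0 fell (the same adjusted over the list alone), and COX1 stood at −0.09 (limma adjusted p = 0.0679, and 0.0176 with batch as a block), and it also passed after rescaling to TPM, with limma-voom, with weights per library and without knockdown library 3. The calls of ND1, ND2 and ND4 were lost under quantile normalization, and those of ND2 and ND4 also without the filter. Of the mitochondrial genes, 6 rose and 1 fell with batch as a block, 7 and 0 under median centring and 1 and 1 under quantile normalization. The mitochondrial list did not pass (median 0.09, camera adjusted p = 0.0756) except with batch as a block (adjusted p = 0.0498) and without scrambled library 3 (0.0403) or knockdown library 1 (0.00717). Its summed level was 11573 ± 338 FPKM in scrambled and 12212 ± 623 in knockdown libraries (SD, n = 3 each). Of 9 tested histone genes, whose transcripts mostly lack a poly(A) tail and whose copies share reads, 2 rose and 1 fell (the same adjusted over the list alone), with H4c4 (0.45) and H4c2 (0.82) higher. The histone that fell was H1f0 (−0.40), a linker histone that is not replication-dependent although it stood in that list. H3c3 stood at 0.41 (limma adjusted p = 0.0731, and 0.0115 with batch as a block) and also passed under median centring, under quantile normalization, with weights per library and without knockdown library 3. The calls of H4c4 and H4c2 were lost without the filter. That of H4c4 was also lost with limma-voom and without scrambled library 1, and that of H4c2 without scrambled library 2 or knockdown library 1. The list did not pass (median 0.01, camera adjusted p = 0.505).

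Few markers of other cell types were abundant enough to test. Macrophage markers summed to 7.45 ± 1.07 FPKM in scrambled and 6.62 ± 0.279 in knockdown libraries, and of the 3 tested Cd74, which is also induced by interferon, fell by 1.34, Cd14 rose by 0.35 and Cd68 stood at −0.03 (adjusted p = 0.823), with its sign turned under median centring, under quantile normalization and with the level, length and GC trend removed. The list had a median of −0.03 and a camera direction of up (adjusted p = 0.952). Lymphocyte and mast cell markers summed to 0.223 ± 0.0505 and 0.106 ± 0.0745 FPKM, and none of the 8 listed was abundant enough to test. The 1 tested endothelial marker, Egfl7, fell by 0.46 (5.20 ± 0.305 to 3.66 ± 0.253 FPKM), and the 1 tested neural marker, Tubb3, fell by 0.46 (26.4 ± 0.623 to 19.1 ± 1.56 FPKM). Neural markers summed to 27.6 ± 0.560 and 19.9 ± 1.54 FPKM in scrambled and knockdown libraries, nearly all of it Tubb3, and epithelial and mesothelial markers to 93.1 ± 5.36 and 97.3 ± 0.146 FPKM, nearly all of it Krt19 and Msln. Of 2 tested epithelial and mesothelial markers, Krt19 rose by 0.24 and Msln fell by 0.52, with overlapping groups for Msln (22.5 ± 4.36 and 15.4 ± 2.27 FPKM) and its call lost without the filter and without scrambled library 1, scrambled library 2 or knockdown library 1. The counts of these 4 tested lists were the same adjusted over the list alone.

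Across the 25 lists tested as a whole, 9 passed the threshold with the preset correlation, 4 of them up and 5 down, while 0 passed with an estimated correlation and 10 passed with batch as a block. Other splits of the same 6 libraries into 3 and 3 gave between 5 and 10 lists past the threshold with the preset correlation. Each of these splits mixes libraries of both groups in unequal numbers, so it still holds part of the group difference. Their counts do not show how many lists pass without such a difference, so they are no check of the p-values with the preset correlation. The estimated correlation between genes was above the preset of 0.01 in each of the 9 lists that passed. It ran from 0.127 for extracellular matrix to 0.493 for the integrated stress response. By these estimates, which rest on 6 libraries, the preset was too low for these lists and their p-values with it are too small. The median was larger in size than in each of the other splits for 15 of the 25 lists, which include 8 of the 9 that passed, all but the smooth muscle list, and 7 that did not pass. It was −0.87 against at most 0.41 for interferon-stimulated genes, −0.52 against 0.20 for the integrated stress response and 0.37 against 0.17 for ribosome biogenesis. Smaller medians in the other splits follow in part from the mixing of the groups, so this comparison is no test against chance.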

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

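The 2 added settings, limma-voom and removal of the trend with level, length and GC content, were chosen after the results had been seen. Against 5255 genes past the threshold, 128 of them changed at least 2-fold, leaving out 1 library gave between 4335 and 5284 genes and between 115 and 159 changed 2-fold, and Ifit1 stayed between −1.39 and −1.20. The genes changed at least 2-fold numbered 214 (31 higher, 183 lower) with a pseudocount of 0.1, and the lower ones 73 with a pseudocount of 1. A mean FPKM of at least 5 left 2042 genes lower, with 47 changed 2-fold (9 higher, 38 lower). Rescaling to TPM gave 199 (180 lower), quantile normalization 35 higher, limma-voom 249 (35 higher, 214 lower) and the removed trend 28 higher and 69 lower. With an estimated correlation 0 gene lists passed, against 9. The ribosomal protein genes, with a median of 0.12, were at −0.00217 once the trend was removed. Among all genes past the threshold, 4 were called in the opposite direction under quantile normalization and 4 with the trend removed. The other turns among named genes and lists were in values that did not pass. Camera direction of a list (median in brackets) or sign of a gene turned for the osteogenic list without the filter (−0.00603), for cell cycle (−0.0114) and histones (−0.0505) at a mean FPKM of at least 5, and for cell cycle after rescaling to TPM (−0.0566). Median centring turned Runx2 (0.0520), Cd68 and with it the macrophage list (0.0372), and protein folding in the endoplasmic reticulum (0.0326). Quantile normalization turned Runx2 (0.0430), Cd68 (0.168), cell cycle (−0.0382) and oxidative phosphorylation (−0.0248), and the removed trend Gata6 (0.0369), Runx2 (0.0513), Cd68 (0.222), cell cycle (−0.0434) and oxidative phosphorylation (−0.0372). Without single libraries, Runx2 and the osteogenic list ran from −0.0438 to 0.0112, Cd68 and the macrophage list from −0.0730 to 0.0472, and protein folding from −0.0512 to −0.0204. Medians near 0 also changed sign under an unchanged camera direction, among them the cardiac list without the filter (−0.00490), the immediate early list after rescaling to TPM (−0.000233) and without scrambled library 3 (−0.00332), oxidative phosphorylation after rescaling to TPM (−0.0216) and cell cycle under median centring (0.0545). With batch as a block 5229 genes and 10 lists passed, the list gained being the mitochondrially encoded genes, COX1 and H3c3 passed, and the macrophage list (−0.0287) turned in camera direction. The cause was not tested.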

Other observations

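The tests below were chosen after the results had been seen, and the sets of Gene Ontology and Reactome were also tested after that. ADSCs with less Ifit1 RNA had lower RNA of interferon-stimulated genes, of MHC class I antigen presentation, of integrated stress response genes such as Trib3, Cth, Asns and Ddit4, of hypoxia and glycolysis genes and of extracellular matrix genes, and higher RNA of ribosome biogenesis genes and translation factors. As lists, all of these lost their call with an estimated correlation (camera adjusted p = 0.284 each). Ribosome biogenesis, with 34 of 35 genes higher, had an unadjusted camera p of 0.0618 in that setting. A list that did not pass there is thus not shown to be unchanged. Of 1891 Gene Ontology and 708 Reactome sets tested, 142 and 213 passed with the preset correlation, 54 and 34 of them lower in knockdown. Sets of lipid genes were among the lower ones, while the adipocyte list fixed beforehand did not pass (camera adjusted p = 0.0671). Of 63 genes of cholesterol metabolism 42 fell and 4 rose (camera adjusted p = 6.35e-05, and 1.9e-05 with the trend removed), and of 35 genes of fatty acid beta-oxidation 27 fell and 0 rose (adjusted p = 5.26e-05, and 1.9e-05 with the trend removed). None of the Gene Ontology or Reactome sets passed with an estimated correlation, the smallest adjusted p being 0.814 and 0.385. Myogenic genes were mostly too low to test, so the data say little on muscle differentiation.

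The split into knockdown and scrambled was compared with the other ways of parting the 6 libraries into 3 and 3. Of 10 splits, 1 gave 5255 or more genes past the threshold, the highest other giving 0, and 1 gave 128 or more genes changed at least 2-fold, the highest other giving 0. Of the 10 splits 6 gave 9 or more gene lists, the highest other giving 10. The 3 other splits that also part all 3 batches gave 0 genes and 6, 8 and 9 lists. With 10 splits the share cannot go below 0.1, so chance cannot be excluded this way. For the number of lists the real split did not stand out. The other splits mix both groups in unequal numbers and still hold part of the group difference, so the number of lists decides nothing here.

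The fall of the interferon-stimulated genes was set against a trend in level, length and GC content, macrophages and the hairpin itself. With the trend removed the median was −0.70, so that trend does not account for it. The summed fall of Lyz2, Tyrobp, Fcer1g, Laptm5 and Ptprc was −0.0656% of the fall of Isg15, a slight rise. With means of at most 0.107 FPKM in either group, loss of macrophages bearing these genes does not account for it. The whole macrophage list summed to 7.45 ± 1.07 FPKM in scrambled and 6.62 ± 0.279 in knockdown libraries, and other immune cells were not part of this test. Ifit1 is itself an interferon-stimulated gene, and 25% of the list fell by a larger factor than Ifit1 did, so its fall could be part of a lower interferon response rather than the work of the hairpin. Without untransduced cells the effects of Ifit1 loss, of either hairpin and of culture remain open.

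The fall of the integrated stress response genes had a median of −0.47 with the trend removed, so the trend does not account for it. Denser or more depleted scrambled cultures might raise these genes together with those of hypoxia and glycolysis, whose median was −0.38 in knockdown. Such cultures would also hold fewer dividing cells, but the cell cycle list did not pass (median −0.01, camera adjusted p = 0.571, with 8 genes higher and 9 lower). The prediction was thus met only in part. That balance depended on the scaling, with 14 higher and 7 lower under median centring and 3 and 14 after rescaling to TPM, so it weighs little. Cell density and medium are not given in the sources used here, so this remains open beside an effect of Ifit1.

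The lower level of rare transcripts in knockdown was not due to depth, since a gap of 470 genes above 0 remained after all libraries were thinned to the smallest. DNA background would take the same amount from all genes, but genes of FPKM 0.5 to 1 lost 24.5 times the scrambled level of genes under 0.02. Scaling by a few abundant genes would shift all other classes alike, but the ratio of genes of FPKM 10 to 100 exceeded that of genes under 0.1 by 4.86 SD. The data do not tell whether RNA quality, library preparation or Ifit1 caused it.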
